A study of Mus musculus with 6 samples.

How the data were processed

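RNA of mouse spleen cells, prepared and labelled by the submitters, was measured on Illumina mouse bead arrays. Per the labels, the 6 arrays were macrophages, CD8+ cDC and CD8- cDC of strain C57/B6, each with replicates 1 and 2. How the cells were isolated, and the age and sex of the mice, are not given in the sources used here. The submitters' processing notes name BeadStudio and limma, without versions or roles.

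The deposited values were used as they came, in log2 per the values themselves: the labels do not state the base, and it was inferred from the range of the table. The 6 columns of the authors' value table held 45281 probes and had nearly the same distribution, with a largest gap of 0.0349 between sorted columns. They were therefore taken to have been quantile-normalized before deposit, which the labels do not state. Of all values, 60.5% lay under 5 log2. No further normalization was done for the results above.

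The design written before the files were seen planned to start from the scanner signals, with detection p-values as a filter. The 12 columns of that table have names that match none of the samples' labels, so it was not used here. The value table replaced it, all of its probes were tested, and no detection p entered. The tests, comparisons, thresholds, gene lists and named-gene rule were fixed before the data were examined. The background level was chosen after the data were seen.

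That level was the 99th percentile (5.25 log2) of the values of 1589 probes for olfactory, vomeronasal and taste receptors and keratin-associated proteins. A lower level, the 95th percentile (4.91 log2), served as an alternative. The level decided which genes were given as a minimum fold and which were said to be at background, and it did not filter the tests. A called gene with any array of the dimmer side at or under it was given as a minimum fold, each such array being counted at the level. Genes were still picked and ranked by the unbounded log2 difference, and counts of at least 16-fold differences use it too.

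Probes were named by the deposited annotation: 34885 had 1 gene symbol, 18 several and 10378 none. The gene table of assembly GRCm38.p6 was used for names only. It held the gene IDs of 34807 probes and changed 0 symbols. Probes with several or no symbols stayed in the adjustment and were not named. Where a gene had over 1 probe, as 9172 did, the probe with the highest mean over all 6 arrays stood for it, which left 19057 genes. Of 1775 called genes with over 1 probe in the contrast of macrophages and cDC, all probes were called for 377, and in 11 genes probes were called in both directions. Between CD8+ and CD8- cDC these counts were 26 of 236, and 0 genes.

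All 6 arrays were fitted together with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 1 coefficient per group, which left 3 residual degrees of freedom and a prior of 1.86. Contrasts were macrophages minus the mean of both cDC groups, CD8+ minus CD8- cDC, and macrophages minus each cDC group. P-values were adjusted by the method of Benjamini and Hochberg over 45281 probes, and a gene was called when the adjusted p was under 0.05. Every adjusted p given for a gene is limma's. The labels give all groups the numbers 1 and 2 without saying what they share. Replicate differences of probes above background correlated at 0.421, 0.281 and 0.287 between the groups, so the numbers may pair the arrays. The main fit and the list tests did not account for such a pairing, and a fit with the number as a block was made as well. A gene counted as higher in 1 population than in both others when both pairwise contrasts were called with a log2 difference of at least 1.

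The 37 gene lists, written before the data were examined, held 711 entries, of which 663 were measured under the same name or an older alias. The other 48 had no named probe and were not analysed here. Lists were tested with camera in limma, with a preset inter-gene correlation of 0.01, adjusted over the 37 lists within a contrast. Camera with an estimated correlation and the rotation test fry were run as alternatives. With an estimated correlation, camera tests against the 3 residual degrees of freedom, so few lists could pass with these arrays. Between macrophages and cDC fry called 22 lists, 20 of them also called by camera, and between CD8+ and CD8- cDC it called 4, all also called by camera. Members were counted as called over all probes, and also adjusted over the list alone.

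Genes were named by a fixed rule. For each main contrast these were the 12 highest and 12 lowest called genes whose arrays did not overlap between sides, and for each pairwise contrast the 5 highest and 5 lowest. Per population the 6 genes with the largest smaller difference were taken, per list up to 4 members with the largest differences, and 16 defining genes were always taken. Not all genes picked are printed, and further list members were added to give examples.

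The steps were tested on simulated data with the same number of arrays. Of 100 genes changed by log2 1 between macrophages and cDC 12% were called, and of 100 changed by log2 2 44%, with 1 false call. Between CD8+ and CD8- cDC 2% and 25% were called, with 0 false calls. Camera gave a moved list an adjusted p of 2.2e-28 and called 0 of 30 unmoved lists. Many real differences of 2-fold or 4-fold would thus be missed with these arrays. The simulated noise was independent between probes, without correlated list members or replicate differences. The false calls and unmoved lists therefore do not measure the error rate on the real arrays.

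Alternatives covered thresholds, moderation, array weights, the replicate number, the arrays in the fit, the probe per gene, filters on dim probes and scaling. Splice forms, gene networks and pathway databases were left out.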

Results

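RNA from mouse (C57/B6) spleen was measured on an Illumina bead array in 3 cell populations: macrophages, CD8+ conventional dendritic cells (cDC) and CD8- cDC. Each population had 2 arrays, 6 in all, so every group mean below rests on n = 2 and its standard deviation (SD) is poorly known. The labels do not say whether the replicates came from separate animals, sorts or cultures, and the p-values measure only the spread between these samples. Values are log2 signals; a difference is given in log2 units with its standard error (SE), and a level as mean ± SD.

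Between 15802 and 15827 of 45281 probes lay above the background level of 5.25 log2 on each array. That level was set from probes of genes taken to be silent outside sensory organs and hair follicles, such as olfactory receptors. Replicate arrays had Pearson correlations of 0.963 in macrophages, 0.969 in CD8+ cDC and 0.973 in CD8- cDC, over the 15952 probes used for this comparison. The first principal component held 66.6% of the variance and separated macrophages from both cDC groups. The second held 18.8% and separated CD8+ from CD8- cDC. The third, with 8.06%, separated the arrays numbered 1 from those numbered 2.

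**Figure D1:**
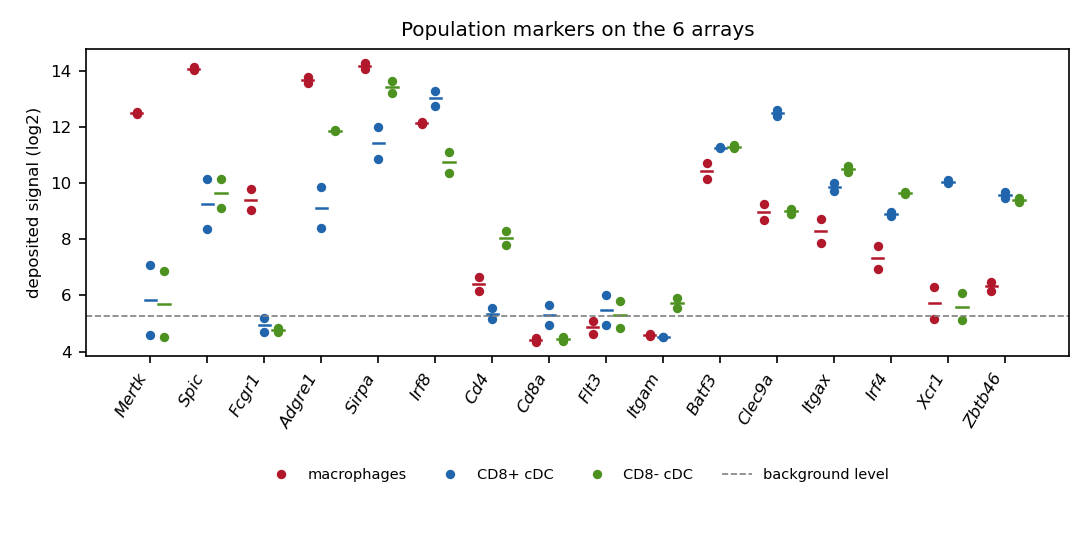
Log2 signal of macrophage, cDC and subset marker genes on each of the 6 arrays. Among them, Spic had a mean of 14.09 in macrophages and Xcr1 a mean of 10.06 in CD8+ cDC.

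Splenic macrophages differed from cDC in genes for haem recycling, clearance of dying cells, complement and antigen presentation. Spic, the transcription factor required for red pulp macrophages, was 4.64 higher in macrophages than in the mean of both cDC groups (adjusted p = 0.0116), at 14.09 ± 0.08 against 9.26 ± 1.25 in CD8+ and 9.64 ± 0.72 in CD8- cDC. Mertk, a receptor for apoptotic cells, was at least 83.4-fold higher (adjusted p = 0.0168), at 12.50 ± 0.06 against 5.85 ± 1.76 and 5.71 ± 1.66. Fcgr1, the high-affinity IgG receptor, was at least 17.8-fold higher (adjusted p = 0.00206). Where any array of the dimmer side was not above background, the fold is given in this way, as a minimum with that array counted at the background level. Where taking the replicate number as a block changed the call of a gene or list whose own result is printed, the adjusted p of that fit is given as well. Counts of called list members are those without the block, and some members behind them changed. In macrophages against cDC the neutrophil marker S100a9 gained a call (adjusted p = 0.0111) and the plasma cell marker Xbp1 lost its call (adjusted p = 0.0519). Zbtb46, a transcription factor of the cDC lineage, was 3.18 lower in macrophages (log2 difference -3.18, SE 0.12, adjusted p = 0.00108), at 6.32 ± 0.21 against 9.58 ± 0.13 and 9.41 ± 0.11.

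Of 19057 genes, 1566 were higher and 1374 lower in macrophages than in cDC, together 2940 or 15.4%. The median size of the called differences was 1.33. At least 16-fold differences numbered 117 higher and 1 lower against the mean of both cDC groups, 119 and 22 against CD8+ cDC, and 124 and 18 against CD8- cDC. The organic anion and drug transporter Abcc3 led with at least 92.2-fold (adjusted p = 0.00957), at 12.48 ± 0.36 in macrophages. The terminal complement component C6 was at least 84.1-fold higher (adjusted p = 0.0104), the glutamate transporter Slc1a3 at least 83.2-fold (adjusted p = 0.0126) and the sugar transporter family member Slc45a3 at least 79.2-fold (adjusted p = 0.00654). Scamp5, a secretory vesicle membrane protein, was at least 63.7-fold higher (adjusted p = 0.00452), and Paqr9, a progestin and adipoQ receptor family member, at least 64.9-fold (adjusted p = 0.0032), with 1 and 2 of the 4 cDC arrays above background. Haemoglobin scavenger receptor Cd163 was at least 75.4-fold higher (adjusted p = 0.0284), and mannose receptor Mrc1, above background on all arrays, was 6.27 higher (SE 1.01, adjusted p = 0.0239). In cDC, Abcc3, C6, Mertk and Slc1a3 each lay above background on only 1 of 2 arrays per group, and their cDC levels had SDs from 1.15 to 1.76.

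On the cDC side, the largest difference was in the lectin-like receptor Klri1, lower in macrophages by 4.19 (log2 difference -4.19, SE 0.53, 18.2-fold, adjusted p = 0.0121). The fatty acid receptor Ffar4 differed by -3.97 (15.7-fold, adjusted p = 0.0184) and the SLAM family receptor Slamf7 by -3.85 (SE 0.53, adjusted p = 0.0155). Mycl, the Myc family member used by cDC, differed by -3.55 (SE 0.48, adjusted p = 0.0148), at 8.63 ± 1.19 in macrophages against 12.93 ± 0.16 in CD8+ and 11.44 ± 0.14 in CD8- cDC. Slc6a13, a GABA and taurine transporter, differed by -3.71 (adjusted p = 0.0026) and the melanosome trafficking regulator Mreg by -3.52 (adjusted p = 0.0031). Of the genes used to define these cells, Itgax (CD11c) was 1.89 lower in macrophages (log2 difference -1.89, adjusted p = 0.0163) and Irf4 1.92 lower (log2 difference -1.92, adjusted p = 0.012), with a smaller fall in Batf3 (-0.84, adjusted p = 0.0484, and adjusted p = 0.059 with the block). Adgre1, the marker of mature macrophages, was 3.18 higher in macrophages (adjusted p = 0.0137), although CD8- cDC also held 11.88 ± 0.01 against 13.68 ± 0.14 in macrophages. Sirpa was 1.76 higher (adjusted p = 0.0418). Irf8 was not called (0.26, adjusted p = 0.724), nor was Itgam (-0.53, adjusted p = 0.0635). The Itgam probe was at background on both arrays of macrophages and of CD8+ cDC, so it said little about this gene. Xcr1 (at least 4.15-fold lower) and Clec9a (-1.78), markers of CD8+ cDC, were lower in macrophages in this contrast, which averages both cDC groups. The probes of Flt3 (4.87 in macrophages, 5.47 in CD8+ and 5.32 in CD8- cDC) and Cd8a were near background and said little about either gene.

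**Figure D2:**
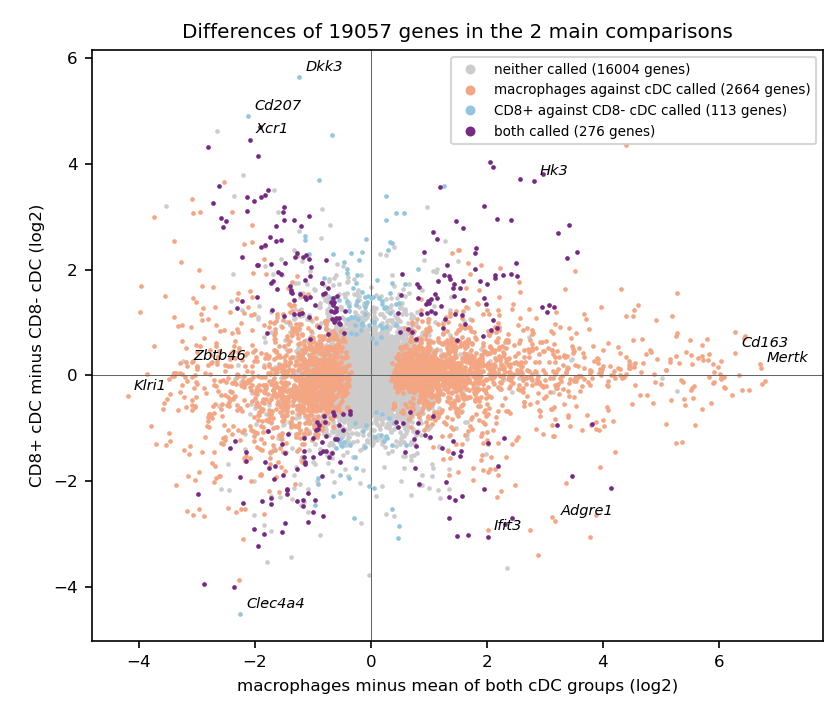
Log2 difference of 19057 genes between macrophages and cDC against that between CD8+ and CD8- cDC. Of these, 276 were called in both contrasts, 2664 only in the first and 113 only in the second.

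Among red pulp macrophage markers, 16 of 20 measured genes were higher in macrophages and 0 lower, with a median difference of 5.28 (19 higher when adjusted over the list alone). That median was 4.53 without CD8+ cDC replicate 1 and 5.87 without CD8+ cDC replicate 2. Camera called the list higher at adjusted p = 1.5e-11, and at adjusted p = 0.342 with an estimated correlation. Itgad (CD11d) was 6.10 higher, C1qa 6.04, haem oxygenase Hmox1 5.81 and the nuclear receptor Pparg at least 35.5-fold. The iron exporter Slc40a1 (3.47) and Axl (4.48) were not called, and Cd5l was at background on all 6 arrays. Core macrophage genes were higher for 18 of 20 (median 3.09), also 18 when adjusted over the list alone, as in Cd14 (5.19), Tlr4 (4.55) and Cebpb (3.34). That list was called at adjusted p = 1.7e-16, and had adjusted p = 0.317 with an estimated correlation. Of 8 marginal zone macrophage markers 5 were higher and 1 lower (6 and 2 adjusted over the list alone). Its higher members included Timd4 (at least 28.9-fold), Marco (4.77) and Siglec1 (at least 7.92-fold), whereas Cd209e was at least 3.62-fold lower (camera adjusted p = 0.0194; adjusted p = 0.34 with an estimated correlation).

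Genes for handling iron and haem were higher in macrophages for 8 of 21 and lower for 1, or 13 and 1 adjusted over the list alone. Biliverdin reductase Blvrb was 4.46 higher and the haemopexin receptor Lrp1 4.17, while transferrin receptor Tfrc was 0.91 lower (log2 difference -0.91). The list test returned adjusted p = 2.5e-05, and adjusted p = 0.317 with an estimated correlation. Complement genes were higher for 10 of 16 and lower for 0 (11 adjusted over the list alone), led by C1qa (6.04, adjusted p = 0.0521 with the block), C2 (6.02) and C1qc (5.53, adjusted p = 0.0691 with the block), while C1qb (5.28) was not called at adjusted p = 0.07. The complement list was called at adjusted p = 5e-05, and had adjusted p = 0.34 with an estimated correlation. Scavenger and apoptotic cell receptors were higher for 11 of 21 and lower for 2 (12 and 2 adjusted over the list alone), with Stab2 5.52 higher. Their camera result was adjusted p = 0.000238, and adjusted p = 0.34 with an estimated correlation. Fc receptors were higher for 6 of 9 and lower for 0 (6 and 1 adjusted over the list alone), among them Fcgr3 (5.54) and Fcgr4 (3.6). This list had adjusted p = 0.000322, and adjusted p = 0.317 with an estimated correlation.

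Lysosomal genes were higher in macrophages for 18 of 28 and lower for 1 (19 and 2 adjusted over the list alone). The asparaginyl endopeptidase Lgmn was 3.22 higher (adjusted p = 0.000935), the peptidase Tpp1 2.99 and cathepsin Ctsc 2.64, and the glucuronidase Gusb was 0.77 lower (log2 difference -0.77). The picked probe of the acid phosphatase Acp2 was 3.16 higher, but probes of Acp2 and of the cholesterol transporter Npc1 were called in both directions. Camera called the lysosomal list at adjusted p = 5.2e-10, and adjusted p = 0.317 with an estimated correlation. Cholesterol and lipid genes were higher for 8 of 18 and lower for 2 (9 and 2 adjusted over the list alone). Nr1h3 (LXR alpha) was 5.72 higher, Apoe 3.85 and lipoprotein lipase Lpl at least 44.6-fold (camera adjusted p = 0.00263; adjusted p = 0.342 with an estimated correlation).

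Core cDC genes were lower in macrophages for 18 of 21, and 19 when adjusted over the list alone (median -3.18). That median was -3.53 without macrophage replicate 1, which held 0.91 more of these genes than replicate 2, and -2.36 without replicate 2. The lower genes included the chemokine receptor Ccr7 (-3.26) and the transcription factor Bcl11a (-3.09). Camera gave adjusted p = 4.3e-13, and adjusted p = 0.34 with an estimated correlation. MHC class II presentation fell in 8 of 14 members and rose in 0 (9 fell adjusted over the list alone). The largest falls were in H2-Ob (-3.35), H2-Oa (-3.28), H2-Eb2 (-3.18) and the class II transactivator Ciita (-2.36), whereas H2-Aa itself was level (-0.03). The class II list had adjusted p = 0.000135, and adjusted p = 0.34 with an estimated correlation. MHC class I presentation was lower for 6 of 19 (8 adjusted over the list alone), as in Psme2 (-1.67), Tapbp (-1.60) and the immunoproteasome subunit Psmb8 (-1.15). Its adjusted p was 0.0041, and adjusted p = 0.342 with an estimated correlation. Costimulation and maturation genes were lower for 6 of 20 and higher for 2 (10 and 2 adjusted over the list alone), with Fscn1 (-2.63) and Cd40 (-2.61) lower and Cd86 1.36 higher. Camera gave adjusted p = 0.00025 here, and adjusted p = 0.342 with an estimated correlation.

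CD8+ cDC markers were lower in macrophages for 9 of 21 and higher for 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00125; adjusted p = 0.342 with an estimated correlation). CD8- cDC markers split, with 4 of 21 higher and 6 lower (4 and 9 adjusted over the list alone), and were not called by camera (adjusted p = 0.0824). In that list Csf1r was 4.21 higher and Tlr7 2.33 higher, while Ltb differed by -2.66 and S100a4 by -2.16. Toll-like receptors and adaptors were higher for 6 of 22 and lower for 2, or 7 and 2 adjusted over the list alone. Tlr8 was at least 4.08-fold higher and Tlr11 2.13 lower (log2 difference -2.13), with camera adjusted p = 0.0327, and adjusted p = 0.428 with an estimated correlation. Cytosolic sensors were higher for 6 of 19 and lower for 2 (9 and 4 adjusted over the list alone), including the adaptor Mavs (2.13) and the bacterial rod protein sensor Naip2 (1.70). The DNA-binding Ifi205 was lower (-3.74), and the sensor list had adjusted p = 0.0331, and adjusted p = 0.428 with an estimated correlation.

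Cell division genes were lower in macrophages for 8 of 28 and higher for 0, and for 21 when adjusted over the list alone. Macrophage replicate 1 held a median of 0.88 more of them than replicate 2. Thymidylate synthase Tyms differed by -2.88 and the kinase Cdk1 by -1.94. For this list camera returned adjusted p = 6.8e-08, and adjusted p = 0.342 with an estimated correlation. Glycolysis genes were lower for 2 of 15 and higher for 1 (6 and 2 adjusted over the list alone). The hexokinase Hk3 (2.81) and the aldolase Aldoc (at least 3.02-fold lower) moved in opposite directions (camera adjusted p = 0.0305, lower; adjusted p = 0.342 with an estimated correlation). Immediate early and stress genes, which respond to cell isolation, were lower for 3 of 30 (3 adjusted over the list alone), as in Dusp2 (-1.65). Their camera result was adjusted p = 0.0234, and adjusted p = 0.643 with an estimated correlation. The median of this list was -0.48, but -0.87 without macrophage replicate 1 and -0.05 without macrophage replicate 2, so its size depended on the macrophage array used. By the median, replicate 1 held more of these genes than replicate 2 in macrophages and in CD8+ cDC, and less in CD8- cDC. Of 26 oxidative phosphorylation genes 1 was higher (Sdhc, 1.71) and 2 lower, without a call of the list (adjusted p = 0.354).

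Interferon-stimulated genes were higher in macrophages for 8 of 26 and lower for 3 without a call of the list (adjusted p = 0.0932). C-type lectin receptors had 7 of 26 higher, such as Clec4n (5.58), and 4 lower (adjusted p = 0.643). Chemokines had 5 of 20 higher and 2 lower (adjusted p = 0.56). The eosinophil chemoattractant Ccl24 was at least 21.2-fold higher, while Ccl5 (-3.13) and Cxcl16 (-2.32) were lower. The chemokine median was -0.0004 and the mean 0.23, so the sign depended on the summary. The same held for transcription factors, with 6 of 25 higher and 6 lower, a median of -0.05 and a mean of 0.45 (adjusted p = 0.943). Among 13 chemokine receptors 1 was higher, Ccr3 (at least 38.2-fold, adjusted p = 0.000935), and 2 lower (list adjusted p = 0.319).

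Markers of other cell types were counted in the same contrast. Erythroid markers were higher in macrophages for 1 of 12 and 3 when adjusted over the list alone. Klf1 was at least 2.71-fold higher, and Slc4a1 (3.46, adjusted p = 0.00858 with the block) and Alas2 (3.38, adjusted p = 0.0122 with the block) were not called (list adjusted p = 0.00333; adjusted p = 0.428 with an estimated correlation). Platelet markers were higher for 3 of 11 and lower for 1 (5 and 1 adjusted over the list alone), with Clec1b at least 9.815-fold higher, Pf4 at least 2.36-fold higher and Cd9 differing by -1.66. The platelet list had adjusted p = 0.00699, and adjusted p = 0.342 with an estimated correlation. Eosinophil, basophil and mast cell markers were higher for 2 of 13, Ccr3 and Prg3 (at least 2.62-fold), also 2 adjusted over the list alone (adjusted p = 0.0477; adjusted p = 0.342 with an estimated correlation). Plasmacytoid dendritic cell markers were lower for 2 of 11, Klra17 (-2.39) and Spib (-1.33), and for 2 adjusted over the list alone (adjusted p = 0.0396; adjusted p = 0.601 with an estimated correlation). Their median was -2.28 without macrophage replicate 1 and -0.18 without replicate 2. Lists not called were those of B cells (1 of 11 higher, Fcer2a at 1.95, adjusted p = 0.755), plasma cells (2 of 10 higher and 2 lower, adjusted p = 0.868) and T cells (1 of 12 lower, Cd8b1, adjusted p = 0.755). NK cell markers (2 of 11 lower, Klrd1 and Prf1, adjusted p = 0.186) and neutrophil markers (1 of 15 higher, Csf3r at least 8.88-fold, adjusted p = 0.1, and adjusted p = 0.0164 with the block) were also not called. The same was true of monocyte markers (2 of 12 higher and 3 lower, adjusted p = 0.243) and stromal and endothelial markers (2 of 18 higher, Stab2 and Pecam1, adjusted p = 0.154). Macrophage replicate 1 held more of several of these markers than replicate 2, by a median of 2.31 for neutrophil, 2.14 for T cell, 1.79 for plasmacytoid dendritic cell, 1.12 for erythroid and 1.10 for monocyte markers.

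Calls in this contrast were limma's moderated test with Benjamini-Hochberg adjustment over 45281 probes at adjusted p under 0.05, and list calls were camera's with a preset inter-gene correlation. All 23 list calls (14 higher, 9 lower) were lost with an estimated correlation, where the lowest adjusted p was 0.317. That form of camera rests on the 3 residual degrees of freedom, so the loss does not by itself point to correlated members. Fc receptors, with an estimated correlation of -0.065, also went from camera adjusted p = 0.000322 to 0.317. Other called lists had estimated correlations far above the preset 0.01, such as red pulp macrophage markers (0.782) and cell division genes (0.427). Camera's p-values with the preset may be too small for such lists. Plasmacytoid dendritic cell markers (0.733), immediate early genes (0.640) and erythroid markers (0.444) were also not called by fry (adjusted p = 0.289, 0.413 and 0.0872). The counts of called members rest on the same arrays and the same correlated genes, so they are not firmer evidence. Over all 19057 genes, 15.4% were called, 1566 higher and 1374 lower.

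**Figure D3:**
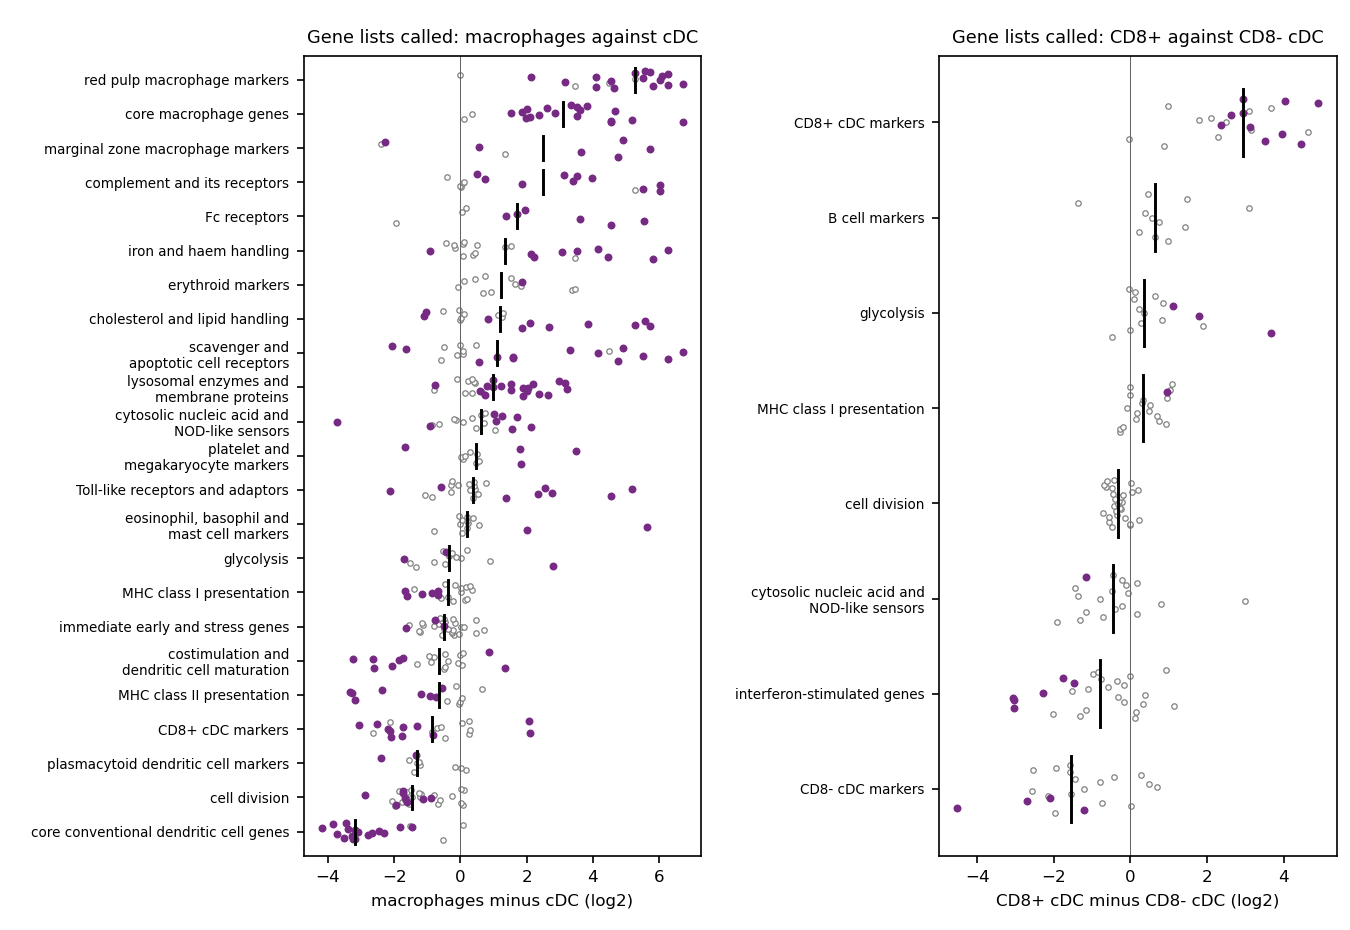
Log2 differences of the members of each gene list called by camera, filled where the member itself was called and with a bar at the median. The widest shifts were in red pulp macrophage markers (median 5.28) and core conventional dendritic cell genes (median -3.18).

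CD8+ and CD8- cDC differed in far fewer genes, among them receptors that mark the subsets. Xcr1, the chemokine receptor for the XCL1 released by T and NK cells, was at least 20.9-fold higher in CD8+ cDC (adjusted p = 0.0344), at 10.06 ± 0.06 against 5.6 ± 0.70. Clec9a, a receptor for actin exposed by dead cells, was 3.51 higher (SE 0.21, adjusted p = 0.0169), at 12.51 ± 0.14 against 8.99 ± 0.12. Langerin (Cd207) was at least 29.7-fold higher (adjusted p = 0.0479), at 10.41 ± 0.13 against 5.51 ± 0.39. On the CD8- side the inhibitory lectin Clec4a4 (DCIR2) differed by -4.51 (SE 0.58, 22.9-fold, adjusted p = 0.0479, and adjusted p = 0.057 with the block), at 11.64 ± 0.01 in CD8- against 7.13 ± 1.26 in CD8+ cDC.

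There were 245 genes higher and 144 lower in CD8+ than in CD8- cDC, together 389 or 2.04% of 19057, with a median size of 1.55, and 271 of the 389 kept their call with the block. The secreted Wnt modulator Dkk3 was at least 37.6-fold higher (adjusted p = 0.0195; 1 of 2 CD8- arrays above background), the collagen prolyl hydroxylase P3h2 at least 21.5-fold (adjusted p = 0.0116), and the VEGF receptor Flt1 at least 16.85-fold (adjusted p = 0.0251). The adhesion molecule Cadm1 was 3.94 higher, at 11.69 ± 0.10 against 7.74 ± 0.67, and macrophages held it at 11.82 ± 0.13. The actin-binding Synpo was at least 10.7-fold higher (adjusted p = 0.0169) and the unnamed transcript 4930455G09Rik at least 11.2-fold (adjusted p = 0.00991). Lower in CD8+ cDC were the calcium release channel Ryr3 (at least 15.2-fold, adjusted p = 0.0399, and adjusted p = 0.0525 with the block), Bex6 (-3.95, adjusted p = 0.0195), the prostaglandin E receptor Ptger3 (at least 7.29-fold), the Ras GAP Dab2ip (-3.03) and the small GTPase Rasl12 (at least 7.42-fold, with 1 of 2 CD8+ arrays above background).

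Of the other defining genes, Cd4 (at least 6.32-fold, adjusted p = 0.0293) and Itgam (at least 1.38-fold, adjusted p = 0.0395) were lower in CD8+ cDC. Itgam was at background on both CD8+ arrays, and its mean in CD8- cDC was only 0.47 above that level. Sirpa (-1.98, adjusted p = 0.128), Irf4 (-0.75, adjusted p = 0.406) and Adgre1 (-2.75, adjusted p = 0.0914) were not called. Irf8, needed for CD8+ cDC, fell short of a call at 2.28 (adjusted p = 0.0528, and adjusted p = 0.036 with the block), with 13.03 ± 0.36 in CD8+ and 10.75 ± 0.54 in CD8- cDC. Batf3 was level (-0.03, adjusted p = 0.997), as was Zbtb46 (0.18, adjusted p = 0.839), and Itgax was not called (-0.64, adjusted p = 0.581). Cd8a, the gene that names the subsets, was not called (adjusted p = 0.263), as its probe read 5.32 ± 0.50 in CD8+ and 4.44 ± 0.09 in CD8- cDC and passed background on 1 of 2 CD8+ arrays. The partner chain Cd8b1 was 1.65 higher in CD8+ cDC (adjusted p = 0.0288). The macrophage gene Spic (-0.38) was not called between the cDC groups, while Mertk and Fcgr1 were above background on only 1 and 0 of 2 arrays in each and were not compared.

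CD8+ cDC markers were higher in CD8+ cDC for 10 of 21 and lower for 0, and for 20 when adjusted over the list alone (median 2.94). Besides those above, the profilin receptor genes Tlr11 (3.11) and Tlr12 (at least 4.29-fold), the CXCR3 ligand Cxcl9 (2.94), Naaa (at least 6.08-fold) and Ppef2 (at least 4.8-fold) were called. Itgae (CD103, 4.62), Gcsam (3.66) and Tlr3 (3.15, adjusted p = 0.0524, and adjusted p = 0.0472 with the block) were not. Camera gave adjusted p = 1.9e-23, and adjusted p = 0.17 with an estimated correlation. CD8- cDC markers were lower in CD8+ cDC for 4 of 21 (12 adjusted over the list alone; median -1.55), with Esam at -2.10. Dtx1 (-2.58, adjusted p = 0.0511) and S100a4 (-2.54) were not called. That list had adjusted p = 4e-10, and adjusted p = 0.17 with an estimated correlation.

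Interferon-stimulated genes were lower in CD8+ cDC for 6 of 26 and higher for 0, or 16 lower and 2 higher adjusted over the list alone. The antiviral genes Oas2 (at least 7.65-fold, adjusted p = 0.03), Ifit3 (-3.05, adjusted p = 0.0497), Oas1g (-3.03), Oasl2 (-2.29), Ifitm3 (-1.76) and Ifi47 (-1.47) were called. Ifit3 read 7.99 ± 0.82 in CD8+ cDC, 11.04 ± 0.14 in CD8- cDC and 11.53 ± 0.25 in macrophages. The interferon list had camera adjusted p = 3.2e-07, and adjusted p = 0.17 with an estimated correlation. Cytosolic sensors were lower for 1 of 19, Casp1 (-1.16), and for 7 with 1 higher adjusted over the list alone. The RNA sensor Ddx58 (-1.91) and the DNA-binding Ifi205 (3.0) were not called (camera adjusted p = 0.000214; adjusted p = 0.578 with an estimated correlation).

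Glycolysis genes were higher in CD8+ cDC for 3 of 15, Hk3 (3.68, adjusted p = 0.0513 with the block), Aldoc (1.78) and Pgk1 (1.11), and for 6 adjusted over the list alone. Camera gave adjusted p = 4.5e-05, and adjusted p = 0.202 with an estimated correlation. MHC class I presentation was higher for 1 of 19, the chaperone Pdia3 (0.96, adjusted p = 0.0549 with the block), and for 8 adjusted over the list alone. The class I list had adjusted p = 0.000399, and adjusted p = 0.584 with an estimated correlation. B cell markers had 0 of 11 called, and 3 higher and 1 lower adjusted over the list alone, with Fcrla at 3.10 and Blnk at 1.49 (camera adjusted p = 0.0086; adjusted p = 0.88 with an estimated correlation). The B cell median of 0.63 was 0.08 without CD8+ replicate 1 and 1.07 without CD8+ replicate 2, so it depended on 1 array. Cell division genes had 0 of 28 called and 0 adjusted over the list alone, with a median of -0.33 (camera adjusted p = 0.0245; adjusted p = 0.925 with an estimated correlation).

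Single members were called in lists that camera did not call. Higher in CD8+ cDC were the chemokine receptor Cxcr3 (2.64), the chemokine Cxcl16 (1.28), the costimulator Cd86 (1.81), Treml4 (1.89), the phagosomal metal transporter Slc11a1 (1.84, adjusted p = 0.0645 with the block), Gusb (2.19) and Vwf (2.01). Lower were Tlr1 (-2.52), Cd300lf (-2.85, adjusted p = 0.0641 with the block) and the fatty acid binding protein Fabp5 (at least 2.66-fold). The chemokine receptor list had 2 of 13 higher (adjusted p = 0.221), the chemokine list 2 of 20 higher (adjusted p = 0.577) and the C-type lectin receptor list 2 of 26 higher and 1 lower (adjusted p = 0.0786). Toll-like receptors and adaptors had 2 of 22 higher and 1 lower (adjusted p = 0.821), and scavenger receptors 2 of 21 higher and 1 lower (adjusted p = 0.577). Costimulation genes had 1 of 20 higher (adjusted p = 0.649), and core macrophage and core cDC genes 0 called (adjusted p = 0.814 and 0.577). Red pulp macrophage markers had 1 of 20 higher and a mean of 0.04 (adjusted p = 0.814), but their direction turned with the array left out: 1.10 without CD8+ replicate 1 (adjusted p = 0.00891) and -1.02 without CD8+ replicate 2 (adjusted p = 0.00969). Plasmacytoid dendritic cell markers had 0 of 11 called with a median of 0.86 (adjusted p = 0.166), which ran from 0.08 without CD8+ replicate 1 to 2.06 without CD8+ replicate 2. MHC class II presentation had 0 of 14 called (adjusted p = 0.941).

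Iron and haem genes had 1 of 21 higher (adjusted p = 0.76), lysosomal genes 1 of 28 higher (adjusted p = 0.821) and lipid genes 1 of 18 lower (adjusted p = 0.726). Platelet markers had 1 of 11 higher, Vwf (adjusted p = 0.285), and T cell markers 1 of 12 higher, Cd8b1, with a median of -0.18 and a mean of 0.01 (adjusted p = 0.815). None was called among complement genes (adjusted p = 0.814), Fc receptors (0.811), marginal zone macrophage markers (0.811), transcription factors (0.811), immediate early genes (0.326) or oxidative phosphorylation genes (0.757), these being camera's adjusted p-values. The same applied to markers of plasma cells (0.384), NK cells (0.183), neutrophils (0.577), monocytes (0.384), eosinophils, basophils and mast cells (0.726), erythroid cells (0.811) and stromal and endothelial cells (0.2). With the replicate block, members of these lists gained a call, namely Cd209b (limma adjusted p = 0.0454), Egr3 (0.0295) and Prf1 (0.0422). Median and mean differed in sign in 5 of the uncalled lists: T cell markers, marginal zone macrophage markers (-0.01 and 0.03), iron and haem genes (-0.01 and 0.02), MHC class II presentation (0.04 and -0.04) and neutrophil markers (0.01 and -0.20).

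The same limma fit and adjustment were used here, and all 8 list calls (4 higher, 4 lower) were lost with an estimated correlation (lowest adjusted p = 0.17). Again this form of camera rested on 3 residual degrees of freedom. The interferon list lost its call too, although its estimated correlation of 0.011 was near the preset 0.01. B cell markers (0.581) and cell division genes (0.427) had estimated correlations far above it, and fry did not call them (adjusted p = 0.463 and 0.816). Fry also did not call cytosolic sensors or MHC class I presentation (adjusted p = 0.123 for each). Calls in this contrast needed all 4 cDC arrays. Without any 1 of them a subset was left with 1 array and the fit with 2 residual degrees of freedom. Such fits cannot tell which of the genes named depend on 1 array.

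Against each cDC group by itself, macrophages had 1249 genes higher and 1001 lower than CD8+ cDC, and 1361 higher and 1131 lower than CD8- cDC. Against CD8+ cDC, Abcc3 (at least 95.6-fold), C6 (91.2-fold), Slc45a3 (86-fold), Mertk (80.45-fold, adjusted p = 0.0502 with the block) and Slc1a3 (77.2-fold) were among the highest, all as minimum folds. The lowest were Ifi205 (-5.24, adjusted p = 0.0141), the antiangiogenic serpin Serpinf1 (at least 30.5-fold lower), the E-cadherin-binding integrin Itgae (-4.96), Ttc39a (-4.96) and the Rac GAP Arhgap22 (-4.81). Against CD8- cDC, Scamp5 was at least 76.5-fold higher (adjusted p = 0.00646), and the anion transporter Slco2b1 at least 93.6-fold (adjusted p = 0.0685 with the block), Slc1a3 89.7-fold, Abcc3 88.9-fold and Mertk 86.4-fold. Here Bex6 (-4.86), Clec4a4 (-4.51), the peptidoglycan-binding Pglyrp1 (at least 20.5-fold lower), Cd7 (at least 19.7-fold lower) and Klri1 (-4.39) were lowest. Adgre1 separated macrophages from CD8+ cDC (4.55, adjusted p = 0.0102) but was not called against CD8- cDC (1.80, adjusted p = 0.104). Sirpa was likewise higher than in CD8+ cDC (2.75, adjusted p = 0.0223). These comparisons used the same macrophage arrays and the same limma fit, so their calls are not independent.

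Each population had genes higher than in both others, by at least 1 log2 unit in both pairwise contrasts. Macrophages had 794, of which 193 were at background in both cDC groups, CD8+ cDC 110 (18 at background elsewhere) and CD8- cDC 77 (18). In macrophages the smaller of both differences was at least 88.9-fold for Abcc3, 77.5-fold for C6 and 77.2-fold for Slc1a3. In CD8+ cDC it was 4.32 log2 for Ttc39a, and at least 21.1-fold for Cd207, 19.45-fold for Xcr1 and 14.3-fold for Flt1. In CD8- cDC it was 4.51 log2 for Clec4a4, 3.95 for Bex6 and at least 15.2-fold for Ryr3. Clec4a4 and Ryr3 lost their call against CD8+ cDC with the block (limma adjusted p = 0.057 and 0.0525). The NK receptor family member Klrb1f, at 7.92 ± 0.01 in CD8- cDC, was at background in both other groups. Independent lists of these sizes would share 58, 7.83 and 5.09 genes by chance, but the contrasts share arrays, so part of the excess may come from that sharing. Simulated groups without differences gave 0 such genes in 20 runs, which does not measure that sharing.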

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

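Counts are higher then lower; changes in a count of over 1.5-fold are listed, and the cause was not tested unless the setting itself fixes it. At adjusted p under 0.01, 730 and 395 genes were called in macrophages against cDC, 1 and 0 in CD8+ against CD8- cDC, 470 and 211 in macrophages against CD8+ cDC, and 564 and 282 against CD8- cDC. Genes higher than in both others were then 374 (macrophages), 0 and 0. With a log2 difference of at least 1, genes lower in macrophages than in cDC were 844. With variances moderated by trend and robustly, CD8+ against CD8- cDC had 440 and 406, and genes of CD8+ and CD8- cDC were 186 and 210. With only the groups compared in the fit, CD8+ against CD8- cDC had 116 and 59, with 640 lower against CD8+ and 746 lower against CD8- cDC. With the mean of a gene's probes, 275 were lower in CD8+ cDC. With a minimum log2 difference of 2, genes of 1 population were 377, 45 and 25.

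With each array left out in turn, macrophages against cDC had 818 to 1319 genes higher and 555 to 1023 lower, against CD8+ cDC 511 to 1133 and 261 to 860, and against CD8- cDC 484 to 1197 and 237 to 940. CD8+ against CD8- cDC had 0 to 116 and 0 to 59, and genes of 1 population were 402 to 757, 0 to 67 and 0 to 40. The 0 counts arose without any 1 of the 4 cDC arrays, where limma still gave 2310 to 2663 genes at unadjusted p under 0.05 (2806 with all arrays). In CD8+ against CD8- cDC the red pulp macrophage markers had a mean of 0.04, which ran from -1.02 without CD8+ replicate 2 (camera adjusted p = 0.00969) to 1.10 without CD8+ replicate 1 (0.00891).

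Further alternatives were chosen after the data were seen. CD8+ against CD8- cDC had 384 and 326 genes with probes above background on 2 arrays, 389 and 330 above the lower level, and 412 and 357 above background on both arrays of a group. Genes of CD8+ and CD8- cDC were then 189 and 193, 193 and 194, and 197 and 201. Cyclic loess on top (1747 and 1120 for macrophages against cDC, 256 and 151 for CD8+ against CD8- cDC) and equal medians moved no count that far. Without both cDC arrays that held more macrophage transcripts, all 11 counts were 0 with 1 residual degree of freedom, against limma's 4506, 2199, 3841 and 3974 genes at unadjusted p under 0.05 in the 4 contrasts.

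A replicate block gave 1754 and 1502 for macrophages against cDC and 240 and 139 for CD8+ against CD8- cDC, but kept only 2691 of 2940 and 271 of 389 of the genes called without it. Of 378 named gene results 14 lost and 23 gained a call under it, and 1 of 74 list results gained 1. Array weights, no minimum difference, and leaving macrophage genes out of the count (221 and 137) changed no count by over 1.5-fold. Not run, because the scanner table was not used, were both background corrections, cyclic loess or median scaling in place of quantile normalization, and both detection filters. The slide as a block was not run, as no slide is named, and the value table and no filter are what the results above use.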

Other observations

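Gene families were compared among 9664 genes above background on at least 2 arrays. Solute carriers were the only family higher in macrophages more often than this whole set, at adjusted p under 0.05. Of 179 Slc genes 48 were higher, where 28.1 would follow from the share of the set (Fisher's exact test, p = 8.7e-05, adjusted p = 0.0402 over 464 tests of 116 families). Fisher's test counts genes as independent, although their calls come from the same arrays, so its p may be too small. Smaller families had larger shares without passing, such as 5 of 10 Aldh genes (adjusted p = 0.618). The carriers move glutamate (Slc1a3, and Slc1a2 at least 10.9-fold higher), monocarboxylates (Slc16a9, at least 55.3-fold), amino acids (Slc7a8, at least 20.4-fold, and Slc16a10, at least 17.5-fold) and potassium with chloride (Slc12a7, at least 9.29-fold). The families and the tests below were chosen only after the result was seen, except the test of scaling and the test of macrophage RNA in the CD8- cDC arrays.

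Some genes were low in 1 population alone. CD8- cDC had 85 genes at least 1 log2 unit below both other groups, among them the lipid phosphatase Plpp1 (4.03 below), Cadm1 (3.94), Rhobtb1 (3.80), the hexokinase Hk3 (3.68) and the actin-binding Lima1 (3.20). Rhobtb1 and Hk3 lost their call against CD8+ cDC with the replicate number as a block (limma adjusted p = 0.0626 and 0.0513). CD8+ cDC had 35, among them Ifit3 (3.05), Dab2ip (3.03), Oas1g (3.0) and the stress-induced Ddit4 (2.81), and macrophages had 376. Some genes followed the replicate number in all groups: of 10620 genes above background, 26 were over 2-fold higher in replicate 1 of all 3 groups, and 2 were lower, Wdfy1 and Erdr1. Erdr1 was above background only in replicate 2, in all 3 groups. Those higher included the lymphocyte genes Cd3g, Thy1 and Cd27, the neutrophil genes S100a8 and S100a9, and the red cell gene Slc4a1.

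Macrophage transcripts were higher in CD8+ cDC replicate 2 and in CD8- cDC replicate 1 than in the other array of each group. Meanwhile 4590 control genes shifted by 0.07 and -0.04. Cyclic loess and equal medians left at least 96.72% of the shift. Both were applied to values that already had nearly the same distribution, so they could hardly change it. Scaling before deposit was thus not tested. Macrophage RNA was tested in 4 forms, all after the shift was seen. Of all 274 bright macrophage genes, 48.5% were higher in both arrays at once. Among those at least 32-fold above the other cDC group, 95.1% were higher in CD8+ replicate 2 and 87.65% in CD8- replicate 1, which restates the shift. The first share counts both arrays jointly and the others 1 array each, so they cannot be compared. Over 881 and 834 genes at background in the other cDC group's less affected array, the rank correlation with the macrophage level was 0.243 and 0.116, the latter under the 0.2 first set, for either array, as excluding macrophage RNA. That bound was changed after 0.116 was seen, because 757 and 723 of these genes were dim, under 8 log2 in macrophages. The split by level was looked at last. It gave medians of 2.33 (7 genes) and 1.82 (8 genes) above 12 log2, and -0.04 (493 genes) and 0.00 (484 genes) under 6. Macrophage RNA in both arrays may be the source (0.116) but stays open, and a change in the cDC themselves was not tested.

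Erythroid markers above background had a median of 1.59 (SD 1.06, 10 markers) in macrophages minus cDC, though only 1 of 12 markers was called without the replicate block. With the block, Slc4a1, Alas2 and Car1 gained a call (limma adjusted p = 0.00858, 0.0122 and 0.026). The list had adjusted p = 0.428 by camera with the estimated correlation and 0.0872 by fry. Erythroid markers were higher in every replicate 1, by a median of 1.12 in macrophages, 0.65 in CD8+ and 0.89 in CD8- cDC. The median difference was 0.86 (SD 0.92) without macrophage replicate 1 and 2.30 without replicate 2. These values include the shift shared with cDC, so they do not show how much rests on 1 macrophage array. In replicate 1 the median level was 8.22 in macrophages, 5.58 in CD8+ and 6.18 in CD8- cDC. In replicate 2 it was 6.32, 4.88 and 5.33. Macrophage replicate 2 alone was above all 4 cDC arrays for 7 of 10 markers. Markers of all other types had a median of -0.0152 (SD 1.59, 81 markers), with lymphoid and plasmacytoid markers at -0.29 (43), monocyte markers at -1.46 (8) and neutrophil markers at 1.16 (9). The neutrophil value came from macrophage replicate 1, with a median level of 7.78 against 4.78 in replicate 2 and 4.64 to 5.78 in cDC. So more cells of other types in the macrophage samples were not excluded, and engulfed or attached red cells were not tested.

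Interferon-stimulated genes above background had a median of -0.96 in CD8+ minus CD8- cDC, with 18 of 23 lower, but 6 of 26 were called. The list call was lost by camera with an estimated correlation (adjusted p = 0.17) and kept by fry (adjusted p = 0.0213). Macrophages held Ifit3 and Oas1g at levels near those of CD8- cDC. Macrophage RNA in the CD8- arrays was therefore tested with the least affected arrays, CD8+ replicate 1 and CD8- replicate 2. The median was -1.12 there, but CD8- replicate 2 still held more red pulp macrophage markers (median level 7.53 against 6.68). Without CD8+ replicate 1 these markers were higher in CD8+ cDC (median 1.38), while the interferon median was still -0.72. The first comparison does not exclude macrophage RNA, and the second, which goes against it, rests on 1 CD8+ array. Plasmacytoid dendritic cell markers had a median of 0.92 in CD8+ minus CD8- cDC, but 0.11 (SD 0.70) without CD8+ replicate 1, so such cells in the CD8- arrays were not excluded. A difference in tonic interferon response between the subsets stays open and untested.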
